A study of Gallus gallus with 4 samples.

How the data were processed

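RNA was sequenced from the area vasculosa of chick embryos at 4 Hamburger-Hamilton stages, with 1 library per stage. Per the labels' protocols, the tissue was dissected from embryos incubated to each stage, total RNA was extracted with Trizol, and libraries followed Illumina protocols on a HiSeq 2000 instrument. Whether embryos were pooled, and how many, is not given in the sources used here. Per the submitters' processing notes, the authors used TopHat2 2.0.8, Cufflinks and Cuffdiff with genome build galGal4. The versions of Cufflinks and Cuffdiff, the gene annotation release and the library scaling chosen in Cuffdiff are not given in the sources used here.

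The deposited table gives FPKM per gene and library (fragments scaled to transcript length and to mapped fragments), per the file headers, with Ensembl gene identifiers, names and loci. For each of the 6 pairs of stages it also gives the authors' p-value and q-value per gene, per the file headers. With 1 library per stage, the authors' p-values rest on no replicate of a stage. FPKM values are not counts, so no count test was run, and neither depth nor a counting interval can be given. An exact 0 can be a failed estimate. There were 27 rows at 0 in HH10 alone with at least 1 FPKM in each other library, against 2, 7 and 15 rows for HH11, HH12 and HH13. Of the 27, 5 lay on chromosome W, 16 on unplaced scaffolds and 6 on numbered chromosomes. All 2, 7 and 15 rows of HH11, HH12 and HH13 lay on numbered chromosomes. Cufflinks loci can span several genes. Of the rows, 2910 share a locus with another row, up to 42 rows on 1 locus, so the coordinates are those of the authors' loci. Starts were printed 1 higher than deposited, since the deposited starts count from 0.

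Of 17108 rows, 3337 had no name, 22 had a name changed to a calendar date by spreadsheet software, and others had names of RNA families or provisional identifiers. The 4788 rows without a symbol were kept under their Ensembl identifiers. The gene name table supplied with the data held no Ensembl identifiers, so it named no further rows. Rows of 1 symbol were summed (76 symbols), which gave 17018 genes. Genes with at least 1 FPKM in at least 1 library were kept, 11773 in all, and values were taken as log2(FPKM + 1). Differences between 2 libraries were described by size, at least 2-fold on that scale, with no p-value.

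The stage trend was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on the stage number, which leaves 2 residual degrees of freedom per gene and treats the stages as evenly spaced. The test was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, and departures from a straight line count as error. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The trend script was tested on simulated data for 11773 genes with residual spreads taken from the real fit, departures from the line included. Of these genes, 200 had a slope, 100 of each size, all among genes above a floor of mean expression. It recovered 38 of 100 slopes of 1 log2 unit per stage and 0 of 100 of 0.5, with 1 false call.

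The 32 gene lists, the tests of the comparisons, the named-gene rule and most alternatives were fixed before the data were examined; some tests of explanations were not, as the closing section says. The lists hold 938 entries, of which 654 were measured, and other members were not analysed here. A list's median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins. This describes these libraries and is not a test across embryos. Bootstrap intervals over members (2000 draws) describe the spread between genes only. The markers of other cell types among the lists were those of neural, cardiac, somite, ectoderm, macrophage and thrombocyte cells.

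Named genes followed a rule. It took the 12 largest higher and 12 largest lower genes with a symbol and at least 5 FPKM in 1 library for HH13 against HH10, 4 and 4 for each adjacent step, and 6 and 6 with the smallest p for the trend. From each list it took the gene with the highest mean and those with the largest differences up and down, and it added the 5 genes with the highest mean FPKM. The values of 1 gene that the rule takes are not reported here. Further list members are named as examples, chosen after their values were seen.

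Alternatives covered pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, 3 other scalings, the highest row per symbol, leaving out each stage, a contrast of the mean of HH12 and HH13 with the mean of HH10 and HH11, robust eBayes, and a 4-fold rule. Alternatives added after the data were seen were HH13 against HH11, leaving out rows on W, Z, unplaced scaffolds and ribosomal RNA, and the libraries labelled HH10 and HH11 exchanged.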

Results

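Gene expression was measured by RNA sequencing in the area vasculosa of the chick embryo at 4 Hamburger-Hamilton stages, HH10, HH11, HH12 and HH13. The area vasculosa is the extraembryonic ring of yolk sac around the embryo in which the first blood cells and vessels form. There was 1 library per stage, so no difference between stages has a replicate check and no value below carries a standard deviation. The number of embryos behind each library was not given in the sources used here. The deposited table held FPKM values for 17108 rows, of which 12320 carried a gene symbol, and 11773 genes reached 1 FPKM in at least 1 library. The number of reads per library is unknown, because FPKM values keep no read count. Total FPKM was 952202 in HH10, 762831 in HH11, 833686 in HH12 and 889136 in HH13, and 10953, 10673, 10799 and 11308 rows reached 1 FPKM. Fold differences are on the log2(FPKM + 1) scale, which understates the difference of genes with low values.

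The HH10 library stood apart in ribosomal RNA and in sex chromosome genes. Rows named 5.8S ribosomal RNA took 5.94% of the total FPKM in HH10, against 0.574% in HH11, 1.03% in HH12 and 1.46% in HH13. The unnamed row ENSGALG00000026592, on chromosome 1 at 100373556 to 100373705 of build galGal4, took 13.3% of the HH10 total, with 126367 FPKM there and 5099, 5613 and 11180 FPKM in HH11, HH12 and HH13. HINTW and WPKCI, known genes of the female-specific W chromosome whose rows here lie on unplaced scaffolds, were both listed at 0 in HH10, and HINTW had 1530, 2389 and 1604 FPKM in the later libraries. ATP5A1W, the W-linked copy of an ATP synthase subunit gene, had 0.654 FPKM in HH10 and 213, 237 and 264 FPKM in HH11, HH12 and HH13. Of the 7 rows placed on chromosome W with a mean of at least 1 FPKM over the later libraries, 6 were listed at 0 in HH10 and the other had 0.0349 FPKM there. Genes on chromosome Z went the other way. Over 537 Z genes, the median log2 difference between HH10 and the mean of the other 3 libraries lay 0.51 above that of autosomal genes, a 1.43-fold difference, with a bootstrap 95% interval over genes of 0.46 to 0.56. The same value over 19 single autosomes ran from -0.04 to 0.04. Mitochondrial rows took 17.2%, 17.5%, 16.8% and 19.4% of the total FPKM in stage order.

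**Figure D1:**
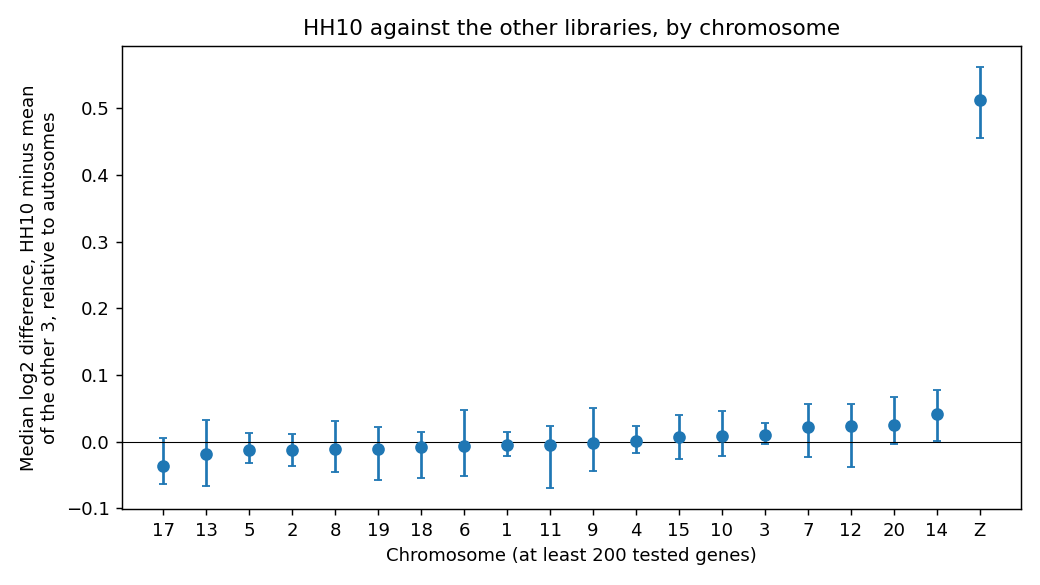
Median log2 difference of the genes on each chromosome with at least 200 tested genes, HH10 minus the mean of the other 3 libraries, relative to the median of autosomal genes; bars are bootstrap 95% intervals over genes. Chromosome Z lies at 0.51, and the 19 autosomes lie between -0.04 and 0.04.

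The first comparison set the last stage against the first, HH13 against HH10. Globin genes showed the greatest difference of the 32 gene lists fixed in advance. HBG1, a beta-type globin on chromosome 1 at 193716133 to 193717673, had 463 FPKM in HH10 and 13730 FPKM in HH13. HBAA, an alpha-type globin, had 729 and 12477 FPKM. All 6 measured globins were at least 2-fold higher in HH13, with a median log2 difference of 4.75 (bootstrap 95% interval over members 4.02 to 5.63). Together the globins took 0.171% of the total FPKM in HH10 and 3.92% in HH13. Globin genes resemble one another, so how the authors' quantification divided reads between them is uncertain. Of 16 measured genes of haem synthesis and iron uptake, 9 were at least 2-fold higher and 1 was at least 2-fold lower, with a median of 1.21. SLC25A37, the mitochondrial iron importer, had 9.90 and 98.0 FPKM, and TFRC, the transferrin receptor, had 68.4 and 178 FPKM. Among 17 red cell membrane genes and erythroid enzymes, 7 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.56. SLC4A1, the red cell anion exchanger, had 1.48 and 129 FPKM, EPB42 had 0.761 and 27.7 FPKM, and the carbonic anhydrase CA2 had 762 and 263 FPKM. AQP1, a water channel of red cells and vessels, had 1.10 and 222 FPKM, a log2 difference of 6.73. Of the 15 measured blood cell transcription factors, 2 were at least 2-fold higher in HH13 and 0 at least 2-fold lower. GATA2 had 87.4 and 93.2 FPKM, and the median of the list, 0.19, lay inside the range of random lists matched on expression. Against HH11 in place of HH10, 7 of the 15 were at least 2-fold higher and 0 lower, with a median of 0.47 inside the range. Against HH12 the median was 0.53, above the range. The thrombocyte list had a median of 0.99 over 11 genes, 5 of them at least 2-fold higher, and TUBB1 had 20.2 and 80.0 FPKM.

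Vessel genes were higher in HH13 as well. Of 27 measured endothelial genes, 16 were at least 2-fold higher than in HH10 and 1 was at least 2-fold lower, with a median log2 difference of 1.17 (0.86 to 1.39). CDH5, the cadherin of endothelial junctions, had 21.4 and 40.9 FPKM, PLVAP had 7.14 and 38.2 FPKM, and CLDN5 had 23.5 and 57.0 FPKM. APLNR, the apelin receptor, was the lower gene, with 38.0 and 13.3 FPKM. The venous list, 3 of whose 6 measured members are also in the endothelial list, had a median of 0.76 (-0.95 to 1.16), with 2 genes at least 2-fold higher and 1 lower, and was not called outside the random range with a filter of 5 FPKM or against HH11. The angiogenic ligands had a median of 0.88, with 8 of 21 genes at least 2-fold higher and 3 at least 2-fold lower, among them CTGF at 5.09 and 31.6 FPKM and IGF2 at 16.8 and 5.18 FPKM. The arterial and Notch list had a median of 0.30 inside the random range, although the gap junction gene GJA5 had 0.188 and 15.5 FPKM. The list of nitric oxide signalling and flow response had a median of 0.44, also inside the range. ASS1, which makes the precursor of arginine, had 39.3 and 230 FPKM. Mural and smooth muscle genes had a median of 1.10, with 9 of 15 genes at least 2-fold higher and 0 at least 2-fold lower. TAGLN had 2.82 and 57.3 FPKM, MYH11 had 0.535 and 17.6 FPKM, and ACTG2 had 83.9 and 398 FPKM.

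Yolk sac endoderm genes formed the next large group. Of 27 measured, 16 were at least 2-fold higher in HH13 and 2 at least 2-fold lower, with a median log2 difference of 1.28 (0.81 to 1.73). The transport proteins APOA1 and TTR had 7827 and 3627 FPKM in HH10 and 21727 and 21632 FPKM in HH13. FGA, a fibrinogen chain, had 21.0 and 217 FPKM. The transcription factor GATA4 went the other way, with 37.9 and 5.34 FPKM. Of 38 basement membrane and matrix genes, 14 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.62. LUM, a small proteoglycan of collagen fibrils, had 5.47 and 164 FPKM, COL3A1 had 11.3 and 198 FPKM, and DCN had 0.686 and 29.7 FPKM. Hox genes had a median of 0.90, with 9 of 21 at least 2-fold higher and 0 lower, and were not called above the random range with a filter of 5 FPKM. HOXB9 had 5.31 and 35.6 FPKM, and HOXB4 had 29.5 and 48.1 FPKM. Oxidative phosphorylation genes had a small median of 0.17, and 42 of 52 members lay above 0. No member of that list was 2-fold apart.

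Other genes were lower in HH13. VENTX, a homeobox gene on chromosome 6 at 21051932 to 21053666, had 24.0 FPKM in HH10 and 0.353 FPKM in HH13. NOG, a BMP antagonist, had 34.3 and 2.34 FPKM, and POUV, a POU-domain factor of pluripotent cells, had 620.5 and 62.5 FPKM. These 3 genes had their highest values in HH11 and were still at 24.4, 40.8 and 473 FPKM in HH12. HTRA1, a secreted protease, had 261 and 31.4 FPKM, LSP1 had 337 and 48.3 FPKM, and VRTN had 70.3 and 9.32 FPKM. The primitive streak list had a median of -0.34, with 4 of 10 genes at least 2-fold lower and 1 at least 2-fold higher, and a bootstrap interval of -1.92 to 0.26. EOMES had 6.52 and 0.131 FPKM, and FGF8 had 1.96 and 6.92 FPKM. That list was not called outside the random range with a pseudocount of 0.1 and at the same total FPKM. The neural list had a median of -0.51, the cardiac list -0.35 and the somite list -0.41, and each lay below the middle 95% of random lists. None of the 3 was called below it with a filter of 5 FPKM, and the somite list, of 6 measured genes, lost its place under 6 more settings. Against HH11 in place of HH10 these medians were 0.18, 0.20 and 0.62. TNNT2, cardiac troponin T, had 23.6, 7.07, 3.79 and 1.97 FPKM in stage order, and SOX2 had 4.16 FPKM in HH10 and 1.24 FPKM in HH13. MYL4, in the cardiac list, went the other way with 21.8 and 380 FPKM. Cell cycle genes had a median of -0.35, with 32 of 37 members not above 0 and none 2-fold apart. CDK1 had 379 and 259 FPKM. The retinoid list had a median of -0.56, which was 0.088 against HH11, and was not called with a pseudocount of 5 or a filter of 5 FPKM. STRA6 had 94.8 and 22.2 FPKM. The Wnt list had a median of -0.23, with RSPO3 at 35.9 and 7.83 FPKM, and was not called outside the random range with a pseudocount of 5, with no filter, with a filter of 5 FPKM and at the same total without globins.

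The remaining lists stayed inside the range of random lists. Their medians were 0.70 for macrophage and leukocyte genes, 0.20 for integrins, 0.19 for lipid handling, 0.17 for immediate early and heat shock genes, 0.12 for ectoderm and epithelial genes, 0.11 for lateral plate mesoderm, 0.07 for ribosomal proteins, -0.12 for glycolysis and hypoxia genes, -0.17 for the BMP and TGF-beta pathway and -0.22 for the hedgehog pathway, whose mean was 0.01. The glycolysis median was 0.01 with every library scaled to the same total without globins. Against HH11 in place of HH10, some lists inside the range lay outside it. The lateral plate median was then 1.29, the macrophage median 1.16 and the glycolysis median -0.43. The arterial and Notch list and the nitric oxide list, at 0.99 and 0.64, also lay above the range there. The macrophage list, a check for another cell type, rested on 7 measured genes, among them RAC2 with 2.60 and 13.0 FPKM. Within the integrins, ITGB5 had 198 and 37.3 FPKM. HAND1, in the mesoderm list, had 98.9 and 396 FPKM.

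**Figure D2:**
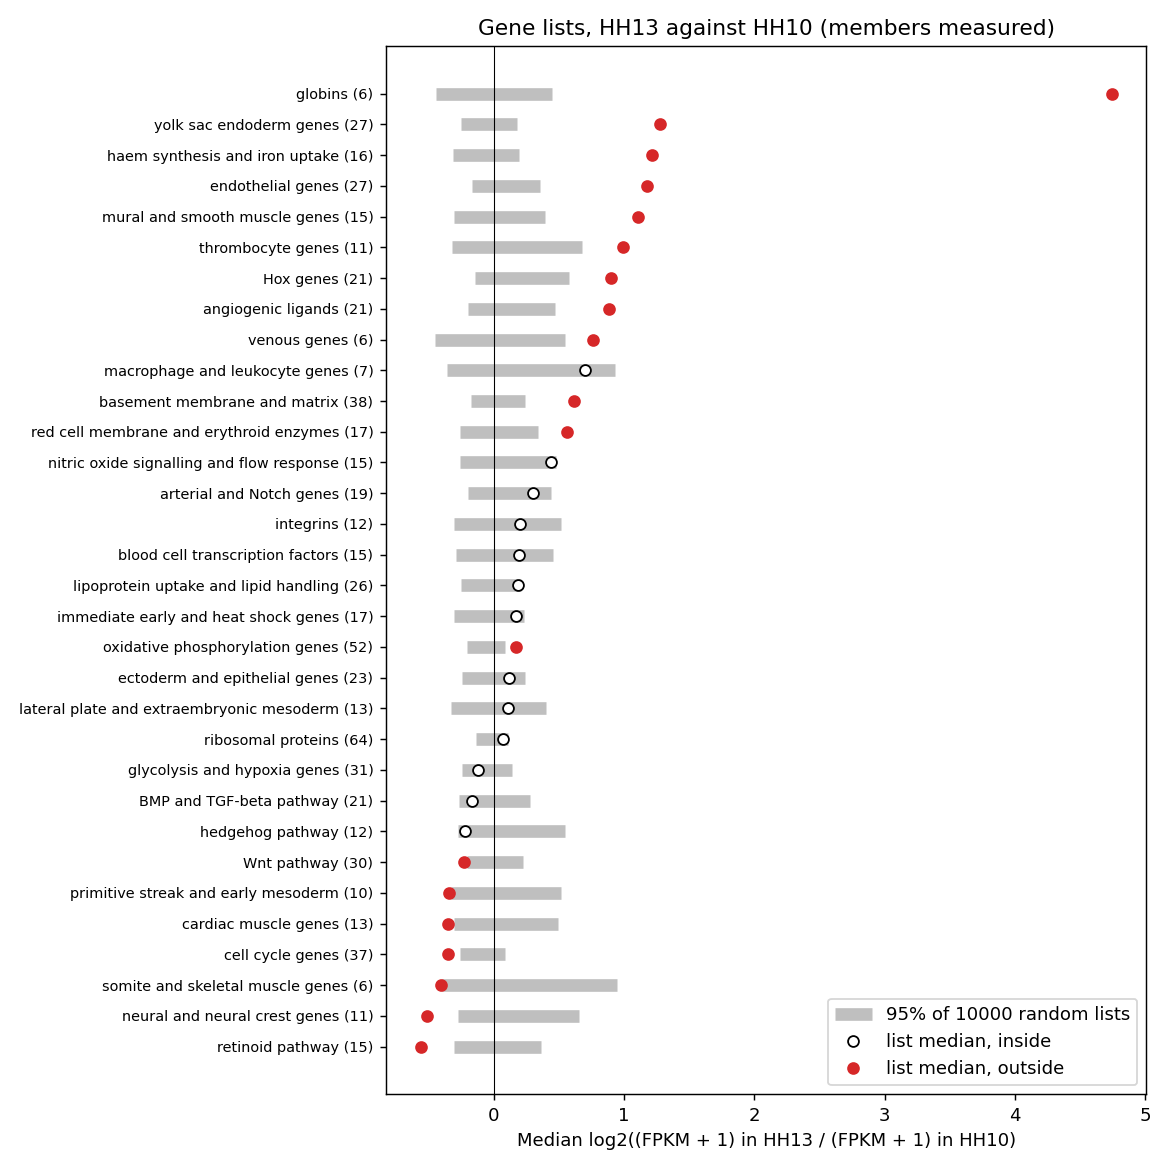
Median log2 difference of each gene list between HH13 and HH10 (points) beside the middle 95% of 10000 random lists of the same size matched on mean expression (grey bars), with the number of measured members after each name. Globins lie at 4.75, 12 lists lie above their bars and 7 lie below.

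In all, 1106 of 11773 genes were at least 2-fold higher and 478 at least 2-fold lower in HH13 than in HH10. Of the 32 lists, 12 lay above the middle 95% of random lists and 7 below it, as a description of these libraries. For lists of genes drawn at random, 1.6 in all would lie outside. Members of a list that vary together between libraries can put more outside, so 1.6 is not the number to be met by chance here. Chromosome Z held 82 of the 478 lower genes, 17.2% against 4.56% of the genes tested, and 28 of the 1106 higher genes. Without rows on W, Z and unplaced scaffolds and ribosomal RNA rows, 1011 genes were higher and 366 lower.

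**Figure D3:**
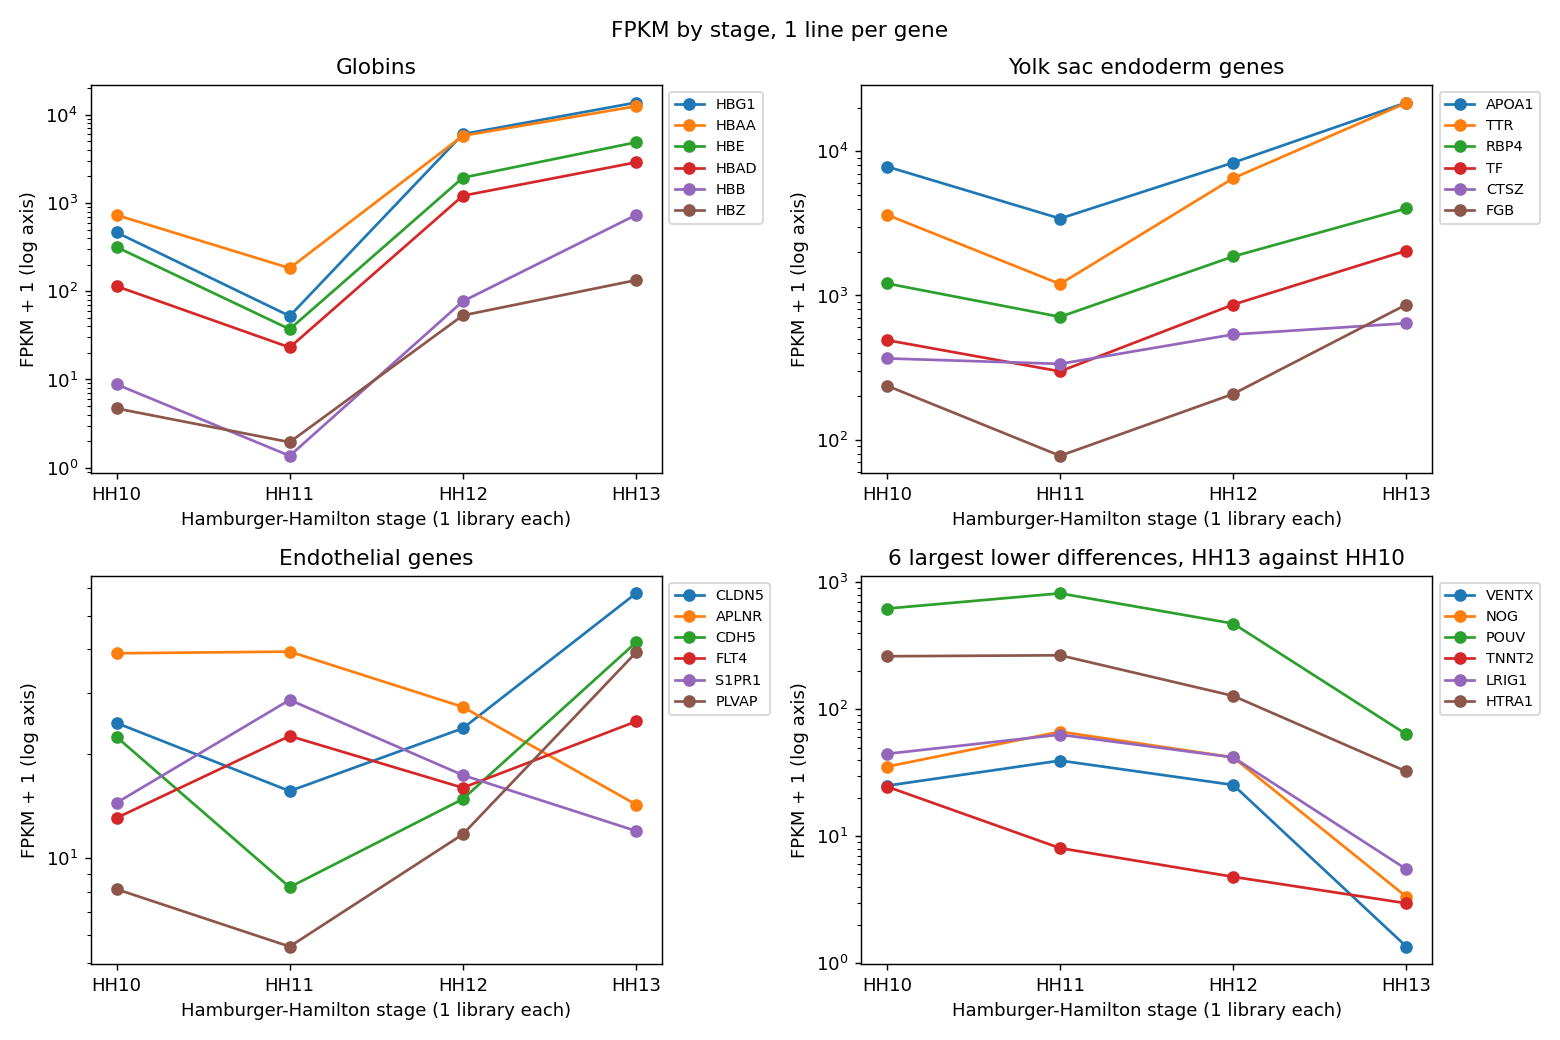
FPKM + 1 by stage on a log axis, 1 line per gene and 1 library per stage, for the 6 globins, the 6 yolk sac endoderm and 6 endothelial genes with the highest mean FPKM, and the 6 genes with the largest lower values in HH13 against HH10. The globins and APOA1 have their lowest value in HH11 and their highest in HH13.

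Adjacent stages gave a different picture at the first step, HH11 against HH10. Globin, endoderm and endothelial genes were lower in HH11. All 6 globins were at least 2-fold lower, with a median of -2.50, and HBG1 had 463 FPKM in HH10 and 51.3 FPKM in HH11. TSPO2, an erythroid membrane gene, had 54.7 and 7.16 FPKM. The endoderm list had a median of -1.13, with 15 of 27 genes at least 2-fold lower, and the endothelial list a median of -0.65, with 8 of 27 at least 2-fold lower. TTR had 3627 and 1199 FPKM, and CDH5 had 21.4 and 7.25 FPKM. The neural, cardiac and somite lists were lower too, at -0.71, -0.60 and -0.77, as were Hox genes, at -0.64. Other groups were higher in HH11. The ectoderm and epithelial list had a median of 0.31, with KRT19 at 2075 and 4053 FPKM. Immediate early and heat shock genes had a median of 0.53, with HSP90AA1 at 488 and 935 FPKM. Glycolysis and hypoxia genes had a median of 0.26, with the glucose transporter genes SLC2A1 at 235 and 540 FPKM and SLC2A3 at 114 and 310 FPKM. EX-FABP, a secreted lipocalin, had 114 and 617 FPKM, and the astacin-like protease gene ASTL had 165 and 790 FPKM. The greatest differences upward were those of HINTW, WPKCI, ATP5A1W and BTF3, the last a row on an unplaced scaffold at 0.115 and 34.8 FPKM. More genes were lower than higher as deposited, and more were higher only with the libraries set to the same total. There were 255 genes at least 2-fold higher and 509 lower as deposited. Median-of-ratios scaling, which divides each library by its median ratio to the gene means, gave 237 and 556. The counts were 543 and 342 at the same total FPKM, and 504 and 319 at the same total without globins. Those totals count ribosomal RNA rows and the unnamed row ENSGALG00000026592, which were high in HH10. The same-total scalings moved the median of all genes by about 0.30 and left the globin, endoderm and endothelial medians below 0.

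At the second step, HH12 against HH11, the same 3 lists were higher in the later stage. The globin median was 5.71, and HBG1 had 6027 FPKM in HH12. The endoderm median was 1.16, with 17 of 27 genes at least 2-fold higher and 1 lower, and APOB had 19.3 FPKM in HH11 and 109 FPKM in HH12. The endothelial median was 0.72, with 9 of 27 at least 2-fold higher and 0 lower. Haem genes had a median of 0.66 and thrombocyte genes of 0.83. EX-FABP was lower, with a log2 difference of -1.97, and NMU, which encodes the peptide neuromedin U, had 10.2 and 0.550 FPKM. The neural list had a median of -0.71 at this step. Over all genes, 520 were at least 2-fold higher and 186 lower as deposited, and 474 and 297 at the same total FPKM.

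The third step, HH13 against HH12, took in more gene groups. Endothelial genes had a median of 1.30, with 20 of 27 at least 2-fold higher and 0 lower, and VWF had 1.45 FPKM in HH12 and 8.51 FPKM in HH13. Arterial and Notch genes had a median of 0.87, matrix genes of 0.85, endoderm genes of 1.24 and globins of 1.29. All 21 measured Hox genes were higher than in HH12, 18 of them at least 2-fold, with a bootstrap interval of the median of 1.16 to 1.90. The lateral plate list had a median of 1.29, with 8 of 13 genes above 0 and a bootstrap interval of -0.20 to 1.67. ATP6V1G3, a proton pump subunit gene, had 0.168 and 27.6 FPKM, and VPAC2, a peptide receptor gene, had 0.521 and 21.0 FPKM. Cell cycle genes had a median of -0.40. Primitive streak genes went both ways, with 4 of 10 at least 2-fold higher and 5 at least 2-fold lower, a median of -0.66 and a bootstrap interval of -1.74 to 1.23. The chemokine genes IL8 and CCL5 had 12.4 and 15.1 FPKM in HH12; IL8 had 0.0494 FPKM in HH13 and CCL5 was listed at 0. In total 1004 genes were at least 2-fold higher and 347 lower. Lists outside the random range numbered 4 above and 14 below at the first step, 7 and 9 at the second, and 17 and 2 at the third.

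**Figure D4:**
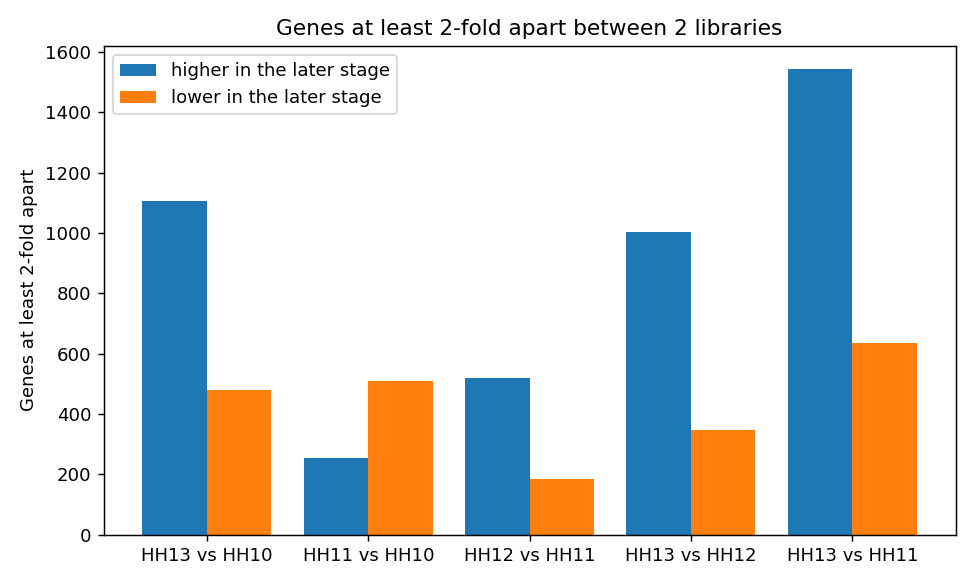
Number of genes with FPKM + 1 at least 2-fold apart between 2 libraries, out of 11773 genes, with genes higher in the later stage beside genes lower in it. Among the 5 pairs drawn, HH11 against HH10 alone had more lower (509) than higher (255) genes. At the same total FPKM, which counts the ribosomal RNA rows high in HH10, there were 342 lower and 543 higher.

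A straight line over the 4 stages asked which genes had a slope with stage number, not whether they moved at each step. The genes with the smallest p among positive slopes were ANXA1, IL1RL1, RGS4, IRF-3, RHOC and CISH. ANXA1, annexin A1, had 6.38, 13.3, 19.8 and 54.8 FPKM in stage order, and RGS4, a regulator of G-protein signalling, had 6.59, 18.6, 29.4 and 45.7 FPKM. Among negative slopes they were TNNT2, MYL3, NOX2, CCDC125, ZOV3 and NUP155. MYL3, a cardiac myosin light chain gene, had 54.0, 39.0, 17.2 and 12.7 FPKM. CCDC125, ZOV3 and NUP155 lie on chromosome Z, and so does ANXA1. limma with Benjamini-Hochberg adjustment called 0 genes over all genes, with a smallest adjusted p of 0.523, and 1111 genes had an unadjusted p under 0.05, where 589 would by chance. Of the 11 other orders of the same libraries, those with the most such genes had 2323 and 1911. On data simulated at this size, slopes were given only to genes above a floor of mean expression. There the test found 38 of 100 genes with a slope of 1 log2 unit per stage and 0 of 100 with a slope of 0.5. Without HH10, limma called 650 genes with positive and 194 with negative slopes. That fit leaves 1 residual degree of freedom per gene, so its error rests largely on the spread shared over genes. Adjusted over the list alone, limma with Benjamini-Hochberg adjustment called 20 genes in 4 of the 32 lists, with no adjustment for the number of lists. These were 4 globins, with positive slopes and adjusted p of 0.0460, and 10 haem genes, of which 9 had positive slopes. All 4 globins were lower in HH11 than in HH10, so these slopes are not a steady rise. In the red cell list SLC4A1, SPTB and EPB42 had positive slopes, SLC4A1 with 2.17 ± 0.43 log2 units per stage (SE) and an adjusted p of 0.0348 by limma. In the cardiac list TNNT2 and MYL3 had negative slopes and MYL4 a positive one, with adjusted p of 0.00506, 0.00506 and 0.0132 by limma over that list.

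The authors compared each pair of stages themselves. At q under 0.05 in the authors' deposited table, 90 rows were higher and 22 lower in HH13 than in HH10, and 156 were higher and 42 lower in HH13 than in HH11. The smaller sets in the authors' deposited table were 29 higher and 13 lower in HH11 than in HH10, 29 and 11 in HH12 than in HH10, 20 and 1 in HH12 than in HH11, and 31 and 26 in HH13 than in HH12. Of the 112 rows called between HH10 and HH13 in the authors' deposited table, 25 had HH10 listed at 0. On chromosome W lay 5 of the 112 rows. Among the 12 genes with the largest higher values in HH13 than in HH10, the authors' deposited table gave q under 0.05 to 4, WPKCI, HBB, LUM and HBAD. For HINTW and HBZ, each summed over 2 rows, no q of the authors' deposited table was taken, so 10 of the 12 were looked up. Among the 12 largest lower ones, the authors' deposited table did so for 6, namely POUV, LRIG1, HTRA1, SLC28A3, VRTN and LSP1, and SLC28A3 lies on chromosome Z. APOA1, with the highest mean of the endoderm genes, had a q of 0.999 between HH10 and HH13 in the authors' deposited table. These q values compare single libraries and hold no measure of the spread between embryos.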

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

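The tests chosen only after the data were seen were HH13 against HH11, the exclusion of W, Z, unplaced and ribosomal RNA rows, and the exchange of the libraries labelled HH10 and HH11. No paired analysis was possible because each stage has 1 library, so the stages share only 1 replicate number. Of the alternative values of the counts that answer a comparison, 99 stayed within 1.5 times and 35 moved further, and of the other values 631 stayed and 104 moved, while 5 more, for lists outside the random range, changed sign; some of the 631 and 104, for lists inside it, changed sign too. None of 420 alternatives of the 48 values behind the genes named for a 2-stage difference changed sign. The limma trend called 1 gene with a positive slope at the same total FPKM, 1 at the same total without globins, and 1 positive and 1 negative for the mean of HH12 and HH13 against that of HH10 and HH11. Leaving out each stage in turn gave 0 to 650 positive and 0 to 194 negative calls, the highest without HH10, and exchanging HH10 and HH11 gave 195 and 12. The cause was not tested. A larger pseudocount and a stricter fold lower the counts by construction. With a pseudocount of 5, higher and lower genes numbered 541 and 207 for HH13 against HH10, 109 and 194 for HH11 against HH10, 228 and 54 for HH12 against HH11, and 403 and 172 for HH13 against HH12. At 4-fold they numbered 248 and 102, 63 and 83, 107 and 33, and 130 and 87 in the same order. With a pseudocount of 0.1, HH11 against HH10 gave 426 and 1025, HH12 against HH11 gave 893 and 407, and HH13 against HH12 gave 1542 higher genes. At the same total FPKM, 543 genes were higher in HH11 than in HH10 and 297 lower in HH12 than in HH11, and without globins in the total 504 were higher and 319 lower in HH11 than in HH10, since a common factor moved every gene. Lists below the random range for HH13 against HH10 numbered 2 with a filter of 5 FPKM and 4 against HH11. The cardiac, somite, neural and retinoid medians changed sign against HH11, to 0.20, 0.62, 0.18 and 0.088, and the somite median was 1.10 with the filter of 5 FPKM. Among lists inside the range, lipid handling, ectoderm, immediate early and heat shock, and hedgehog also changed sign against HH11, to -0.16, -0.13, -0.35 and 0.30, integrins with the filter of 5 FPKM (-0.22), glycolysis at the same total without globins, and lateral plate mesoderm with no filter (-0.01). The cause was not tested. Of the 19 lists outside the random range, 12 stayed outside on the same side with that filter (not the venous, cardiac, somite, neural, Wnt, retinoid and Hox lists), 14 against HH11 (not the venous, cardiac, somite, neural and retinoid lists), and 17 to 19 under the other settings. A list left with under 5 members was not placed, as the globins without unplaced rows. Depth is unknown, so no counting error can be given.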

Other observations

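The tests chosen only after the result was seen were the median of all genes and the neural list, both for HH11 against HH10, and the exchanged order of stages. Single genes of the embryo differed in their course over the libraries. TBX6, a paraxial mesoderm factor, had 4.08, 0.222, 1.07 and 3.83 FPKM in stage order, and FGF8 had 1.96, 0.0957, 0 and 6.92 FPKM. CHRD, which encodes the BMP antagonist chordin, had 3.70, 0.921, 0.440 and 2.75 FPKM, while CDX2, a caudal homeobox gene, had 112, 159, 115 and 44.8 FPKM. In the glycolysis list, LDHA had 103, 398, 176 and 174 FPKM, while its paralog LDHB had 2272, 1081, 2380 and 4191 FPKM. SERPINH1, a collagen chaperone, had 14.4, 62.6, 51.8 and 106 FPKM, and HSPB1 had 0.563, 19.4, 12.4 and 21.4 FPKM. These genes were chosen after their values were seen.

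The HH10 library had almost no signal from rows on chromosome W. Lost reads are argued against: only 0.968% of 3822 autosomal rows at the same level lay as low in HH10 (Wilson 95% interval 0.703% to 1.33%). A prediction written before the result was that a library with no or few female embryos would have higher Z values, and the Z genes lay 0.51 (0.513) log2 units above autosomal genes in HH10. The HH10 sample may therefore have held no or few female embryos, as a hypothesis, since the sex of the embryos was not given. Under it, differences of W and Z genes between HH10 and later stages may be of sex and not of stage.

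Globin, endoderm and endothelial genes were lower in HH11 than in HH10. Scaling is argued against, because it moves every gene by a common factor and all 3 list medians lay below that of all genes, 0.0144. They also stayed below 0 under each scaling. The median of all genes near 0 is no evidence alone, since the authors' scaling is not known. A smaller share of blood, endoderm and vessel cells was first read as possible from the ectoderm list, at 0.31; the test was then reworded, after these values were seen, to the neural list, which lay at -0.711 (interval -1.48 to -0.33), so the lists of other cell types moved apart. Since its outcome was known when it was reworded, that test cannot decide whether such a share was the cause. An exchange of the HH10 and HH11 labels cannot be told apart from a difference between the stages: outside the lists, HH11 lay no farther from HH12 than HH10 did (-0.00230, interval -0.0501 to 0.0470), but farther from HH13 by 0.172 (0.141 to 0.203).

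The number of genes with a stage trend was 0 in the order of the labels. With a count of 0, each of the 12 orders of the 4 stages gives as many by construction, so the count of orders decides nothing, and they are too few for a share under 0.05. The highest other order, HH10 and HH11 exchanged, gave 207.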
